A study of Capra hircus with 9 samples.

How the data were processed

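Mammary tissue of Xinong Saanen goats, 9 samples in 3 stages (3 lactation, 3 dry-off and 3 non-lactation samples, grouped by the source names), was analysed by single-end sequencing of poly(A)-selected RNA, per the labels. The labels do not say whether samples of a stage came from separate animals, so p-values measure the spread between these samples. FastQC is the only tool in the submitters' processing notes; the assembler, aligner and counting method are not given in the sources used here.

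The authors deposited mean RPKM (reads scaled to transcript length and library size) of each stage, with no value per sample, per the file headers. The same deposited table gives a p-value and FDR for each pair of stages, by a test it does not name. The log2 fold changes were recomputed from the authors' means because the deposited log2 columns held spreadsheet errors or infinite values where a mean was 0, and all 3 deposited log2 columns held the stage named second in the header over the stage named first. Depth per sample was not analysed here, so precision from depth is unknown. The authors also deposited pathway members, profile members and the number of correlated transcripts per transcript.

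The design fixed before the data were examined foresaw a model on values per sample and, for group means only, the use of the authors' FDR below 0.05 with no test of expression here; the latter was used. Genes were identified by the authors' protein descriptions. For the 388 symbols on 26 lists fixed before the data were examined, 177 descriptions were matched to 1 symbol by their wording, after the tables and some values had been opened; 172 of these symbols were in the RefSeq gene table and 141 had a transcript in the differential table. A further 38 descriptions that stand for several genes were kept apart as families. The transcript with the highest mean stood for a gene. Reads of near-identical family members and of transcripts in 1 component cannot be told apart.

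Each list's median of log2(mean RPKM + 1), as a difference between stages, was set against 10000 random lists of the same size matched on mean expression in 20 bins, over 1 transcript per component, for lists of at least 3 genes. Percentiles at or below 2.5 or at or above 97.5 are named as outside the limits; they describe these means and carry no p-value. Benjamini-Hochberg adjustment of the authors' p-values over each list gave the counts adjusted over the list alone. These counts cover only genes in the differential table, where 93.8% of transcripts had p under 0.05 in at least 1 comparison. Most members could therefore pass by this selection, and the counts are no independent support for a list. Pathways with at least 10 components were tested with a one-sided exact hypergeometric test against components with a pathway (3694), with Benjamini-Hochberg adjustment. Membership came from the separate pathway table, because the pathway column beside the descriptions shared only 1.07% of its memberships with it. In that separate source, 44 of 44 ribosome members and 49 of 49 proteasome members had matching descriptions; the other pathways were not checked in this way.

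Named genes were chosen by a rule fixed before the data were examined: all measured genes of 5 milk and lipid lists, up to 4 of each other list with the smallest FDR, and the 10 largest rises and falls among transcripts that passed with a mean of at least 10 RPKM in the higher stage. Family descriptions and genes given for comparison were added after the values were seen. Some genes that the rule allows are not reported here.

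In simulated data with no effect, 5.5% of lists of 10 fell outside the limits for dry-off against lactation over 6477 components, and 98.5% did so with a shift of 1 log2. The simulated lists were drawn at random from shuffled values. Their rates do not cover smaller lists or lists whose members vary together. A planted pathway of 40 components, with 90% called against 50%, was found in 100% of runs over 6477 components. The shares called in the data were 63.6% for rises and 0.70% for falls, over 3694 components. Neither setting was simulated, so the power of those tests is unknown. For the spread implied by the 3 p-values, the true values were among the solutions in 99.5% of 200 simulated transcripts. Only 57.5% of these transcripts had a single solution.

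Alternatives were a stricter FDR (0.01), a mean of at least 1 RPKM, at least 2-fold, 1 transcript per description or component, the unadjusted p-value, a pseudocount of 0.1, family descriptions, another pathway background, and centring on the table or ribosomal protein median. One prediction about a mixture of stages was first written as a count of milk transcripts; a second bound, on p-values, was added because the first ignored the spread, after the values were known, and both are reported. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.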

Results

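Messenger RNA was sequenced from mammary tissue of Xinong Saanen dairy goats in 3 stages, with 3 samples per stage. Lactation samples came from day 100 after kidding, dry-off samples from day 310, and non-lactation samples from animals that were neither milking nor pregnant. The question named for the series is which genes of fatty acid metabolism matter in the gland during lactation. The values used here are the authors' mean RPKM of each stage and their pairwise p-values and false discovery rates (FDR), so no value per sample and no depth per sample was analysed here. The differential table held 9131 transcripts of 6477 assembled components, with 3630 distinct protein descriptions. Of these transcripts, 93.8% had a p-value under 0.05 in at least 1 comparison, and how they were chosen from the 51299 transcripts listed is not given in the sources used here. Caseins and fatty acid synthase had no matched transcript in this table and were not analysed here.

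Transcripts of the 2 measured milk protein genes made up much of the summed mean RPKM in lactation and fell at dry-off. In the authors' deposited table LALBA (alpha-lactalbumin, a subunit of lactose synthase) fell from a mean of 60951 RPKM in lactation to 960.4 RPKM in dry-off, a 63.5-fold difference (FDR 0.0239). GLYCAM1, a milk mucin, fell from 11225 to 197 RPKM in the authors' deposited table (FDR 0.0101). The LALBA transcript and both transcripts described as GLYCAM1 together held 49.9% of the summed mean RPKM of the authors' table in lactation, 0.523% in dry-off and 21.5% in non-lactation. Both measured milk protein genes fell, and both also passed when adjusted over the list alone.

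Several genes of milk fat secretion fell as well. In the authors' deposited table butyrophilin, a protein of the milk fat globule membrane, fell from 288 to 5.86 RPKM (FDR 0.0374), a description that can stand for several family members. Another butyrophilin component was listed at 0 in lactation and rose to 1.99 RPKM in dry-off in the authors' deposited table (FDR 0.0323). XDH, the xanthine dehydrogenase of the same membrane, fell from 77.7 to 17.8 RPKM (FDR 0.00779) and RAB18, a lipid droplet GTPase, from 44.0 to 13.1 RPKM (FDR 0.0430) in the authors' deposited table. MUC1, a membrane mucin, had 51.5 RPKM in lactation and 2.76 RPKM in dry-off in the authors' deposited table, with an FDR of 0.0648. Of 3 milk fat globule genes measured, 2 fell, 3 passed when adjusted over the list alone, and the list's median log2 ratio of −2.07 lay at percentile 0.11 of matched random lists.

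Fatty acid uptake genes split by member. In the authors' deposited table LPL (lipoprotein lipase) fell from 39.1 to 1.76 RPKM (FDR 0.00833) and FABP3, a fatty acid binding protein, from 592 to 14.96 RPKM (FDR 0.0328). SLC27A1 and SLC27A3, fatty acid transport proteins, rose by log2 1.13 (FDR 0.0365) and 1.83 (FDR 0.0266) in the authors' deposited table, less than the table median of 2.09, so both lay below that median when centred on it. CD36, a fatty acid translocase, had 82.3 RPKM in lactation and 15.9 RPKM in dry-off (FDR 0.0757), and SLC27A4 had 1.06 and 3.24 RPKM (FDR 0.0753), in the authors' deposited table. Of 6 uptake genes, 2 rose and 2 fell, 6 passed when adjusted over the list alone, and the median log2 ratio of −0.65 lay below all 10000 random lists.

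Of 21 genes listed for fatty acid synthesis, elongation and desaturation, the 8 matched to 1 symbol rose. Some transcripts with family descriptions of this list had lower means in dry-off. ACLY (ATP citrate lyase) rose from 0.685 to 7.05 RPKM (FDR 0.0174) and ELOVL5, an elongase, from 1.34 to 13.9 RPKM (FDR 0.00560) in the authors' deposited table. ELOVL6, ELOVL7, FADS2 and FADS3 rose by log2 2.75, 2.97, 2.24 and 2.23 in the authors' deposited table. ELOVL6 rose from 0.457 to 3.07 RPKM, ELOVL7 from 0.298 to 2.34 RPKM and FADS2 from 0.330 to 1.56 RPKM in the authors' deposited table. The lactation means of these transcripts were thus below 1 RPKM, while FADS3 rose from 2.35 to 11.04 RPKM in the authors' deposited table. MCAT and OXSM, enzymes of mitochondrial fatty acid synthesis, rose by log2 1.48 and 1.93 in the authors' deposited table, below the table median. All 8 genes matched to 1 symbol rose, and 8 passed when adjusted over the list alone. Their median log2 ratio of 1.48 lay at percentile 35.6, within the limits of random lists. Of 9 family transcripts on this list 3 passed the authors' threshold, and these 3 rose. A stearoyl-CoA desaturase description, whose members share sequence, had 179 RPKM in lactation and 25.9 RPKM in dry-off (FDR 0.102) in the authors' deposited table. Acetyl-CoA carboxylase had 7.08 and 3.94 RPKM (FDR 0.141) in the authors' deposited table.

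Cholesterol and sugar genes moved in both directions, while the acyltransferase 1/2 transcripts of the triacylglycerol list that passed fell. A transcript described as glycerol-3-phosphate acyltransferase 1/2, the first step of triacylglycerol synthesis, fell from 28.9 to 5.01 RPKM in the authors' deposited table (FDR 0.0142). DGAT1, the only triacylglycerol list gene matched to 1 symbol, had 1.15 and 1.72 RPKM (FDR 0.0950) in the authors' deposited table and did not pass when adjusted over the list alone. NSDHL, an enzyme of cholesterol synthesis, rose from 5.94 to 15.1 RPKM (FDR 0.0217) in the authors' deposited table, below the table median. Of 6 cholesterol genes 1 rose and 1 fell, 2 passed when adjusted over the list alone, and the median log2 ratio of 0.48 lay at percentile 0.06. SLC2A3 and SLC2A4, glucose transporters, rose by log2 3.14 and 2.47, and UGP2 had 37.8 and 21.3 RPKM (FDR 0.123), in the authors' deposited table. Of 7 lactose and glucose uptake genes 4 rose and 1 (LALBA) fell, 5 passed when adjusted over the list alone, and the median log2 ratio of 0.94 lay at percentile 0.985, or 40.5 with family descriptions, an alternative added after the data were seen.

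Fatty acid oxidation genes that passed all rose. HADHA, of the mitochondrial trifunctional protein, rose from 7.85 to 71.9 RPKM (FDR 0.00296) and CPT2, a carnitine palmitoyltransferase, from 3.38 to 15.5 RPKM (FDR 0.0152) in the authors' deposited table. Of 13 oxidation and lipolysis genes 9 rose, 13 passed when adjusted over the list alone, and the median log2 ratio of 1.21 lay at percentile 1.23 (5.79 with family descriptions), below the table median on the same scale (1.47), although HADHA and CPT2 lay above it. Of 4 lipid regulators 3 rose (SREBF2, MBTPS1 and NCOA1), 3 passed when adjusted over the list alone, and the percentile was 22.8. SREBF1, a regulator of lipogenesis, had 3.50 RPKM in lactation and 3.94 RPKM in dry-off (FDR 0.469) in the authors' deposited table. SLC1A1, a glutamate transporter, fell from 14.9 to 4.50 RPKM (FDR 0.0297) while SLC3A2 rose from 35.9 to 104 RPKM (FDR 0.0117) in the authors' deposited table. Of 3 amino acid transporters 2 rose and 1 fell, 3 passed when adjusted over the list alone, and the percentile was 23.2. EIF4EBP1, an inhibitor of translation initiation, fell from 104 to 63.1 RPKM (FDR 0.0251) while IGF1R rose from 5.15 to 17.4 RPKM (FDR 0.00878) in the authors' deposited table. Of 12 hormone signalling genes 8 rose and 1 fell, 12 passed when adjusted over the list alone, and the percentile was 42.6.

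Macrophage, lymphocyte and fibroblast lists had medians above the limits of random lists. CSF1R, the macrophage growth factor receptor, rose from 6.54 to 92.8 RPKM (FDR 0.00314) and C1QA, of complement, from 24.4 to 288 RPKM (FDR 0.0140) in the authors' deposited table. CD3G, of the T cell receptor complex, rose from 1.20 to 26.1 RPKM (FDR 0.00403) in the authors' deposited table. CD74, the MHC class II invariant chain, rose from 131 to 2004 RPKM in the authors' deposited table (FDR 0.0139). DCN (decorin) rose from 43.5 to 614 RPKM (FDR 0.00374) and PDGFRA from 0.892 to 35.7 RPKM (FDR 0.00498) in the authors' deposited table. Of 10 macrophage genes 7 rose (9 adjusted over the list alone, percentile 99.97), of 8 T and NK cell genes 3 (7, percentile 100), and of 3 B cell genes 1 (3, percentile 99.8). Of 8 fibroblast and matrix genes 6 rose (6 adjusted over the list alone, percentile 99.9) and of 8 endothelial genes 5 (6, percentile 95.8, within the limits). Among all transcripts, 6016 of 9131 were higher in dry-off by the authors' threshold. The counts of rises in these and the other lists are to be read against that share. T and NK cell and B cell genes lay below it, so their medians and not their counts set them apart. Both MHC class II genes and both interferon response genes rose, 2 each adjusted over the list alone, among them IRF7, an interferon regulatory factor, from 3.36 to 25.1 RPKM (FDR 0.00358) in the authors' deposited table.

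Of 17 involution and tissue remodelling genes 11 rose, 14 passed when adjusted over the list alone, and the median log2 ratio of 2.83 lay above all random lists. IL6ST, a cytokine receptor subunit, rose from 2.20 to 27.3 RPKM (FDR 0.00343) and STAT3 from 5.17 to 29.99 RPKM (FDR 0.0428) in the authors' deposited table. Of 11 cell cycle genes 9 rose, 10 passed when adjusted over the list alone (percentile 93.6), with MCM6 rising from 1.24 to 15.1 RPKM (FDR 0.0114) in the authors' deposited table. CDH1, an epithelial cadherin, rose from 7.73 to 49.0 RPKM (FDR 0.00527) and EPCAM had 39.97 and 82.3 RPKM (FDR 0.0682) in the authors' deposited table, so 1 of 2 luminal genes rose and 2 passed when adjusted over the list alone. None of 4 myoepithelial genes passed, also adjusted over the list alone (percentile 21.2). ACTA2, of smooth muscle actin, had 303 RPKM in lactation and 733 RPKM in dry-off (FDR 0.0705) in the authors' deposited table. The 1 adipocyte gene, LIPE, rose, as did 1 of 2 skeletal muscle genes, with 1 each adjusted over the list alone. The 1 neutrophil gene did not pass by either adjustment, and no erythrocyte gene was matched to 1 symbol.

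Among transcripts of at least 10 RPKM in the higher stage, the largest rises were those of Eph receptor B6 (log2 7.69), amphiregulin (5.45), integrin alpha 4 (5.39), PDGFRA (5.32) and complement factor I (5.32) in the authors' deposited table. A calcium/calmodulin-dependent kinase I (log2 5.20), MAP4K1 by its description (5.15), carnitine octanoyltransferase (5.10), GZMB (4.997) and FOXA1 by its description (4.96) followed in the authors' deposited table. These ratios were taken with nothing added to the means, so the ranking favours transcripts with a mean near 0 in lactation. Eph receptor B6 had 0.0514 RPKM in lactation and 10.6 RPKM in dry-off (FDR 0.0340), and GZMB 0.618 and 19.8 RPKM (FDR 0.0441). Besides the milk and lipid genes above, the largest falls were of a V-type ATPase subunit (−2.11), a Ras homolog F description (−1.94) and cysteine dioxygenase (−1.92) in the authors' deposited table. The ATPase transcript belonged to the same assembled component as XDH, so it can share its reads.

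By the authors' FDR below 0.05, 6079 of 9131 transcripts differed between dry-off and lactation, 6016 higher and 63 lower in dry-off. The median log2 ratio over the whole table was 2.09, and 43 cytosolic ribosomal protein transcripts had a median of 1.00. Relative to the table median the same calls split into 3081 above and 2998 below, and relative to the ribosomal protein median into 5792 above and 287 below. The share of higher calls was thus 98.96% as deposited, 50.7% against the table median and 95.3% against the ribosomal median. A rise in RPKM below the table median, as in SLC27A1 or IGF1R, changes sign with the reference chosen.

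**Figure D1:**
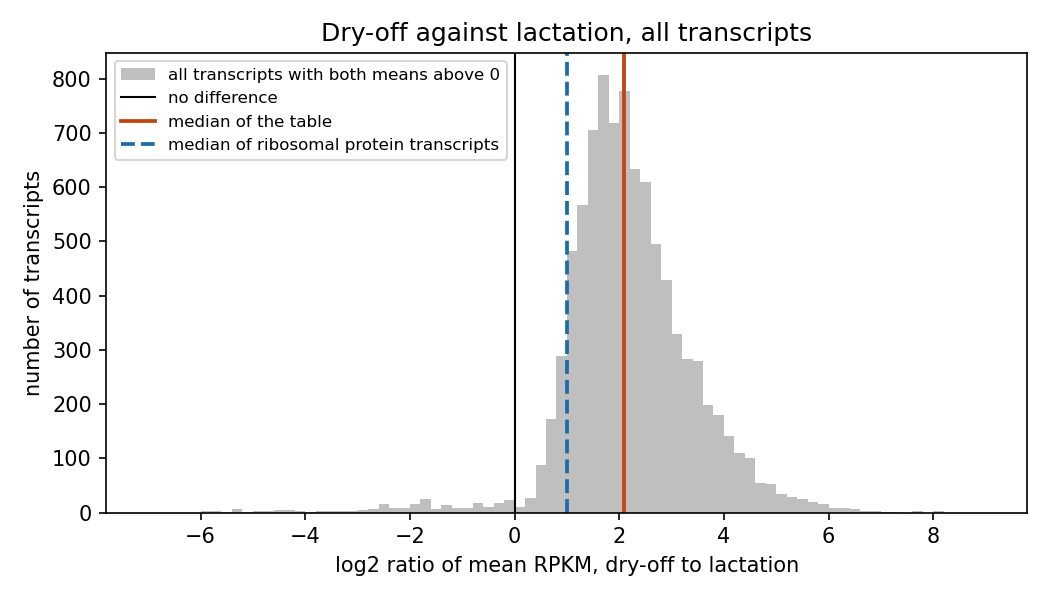
Distribution of the log2 ratio of the authors' mean RPKM, dry-off to lactation, over all transcripts with both means above 0, with the number of transcripts on the vertical axis. The table median (2.09, solid colored line) lies to the right of the ribosomal protein median (1.00, dashed line) and of 0 (black line).

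**Figure D2:**
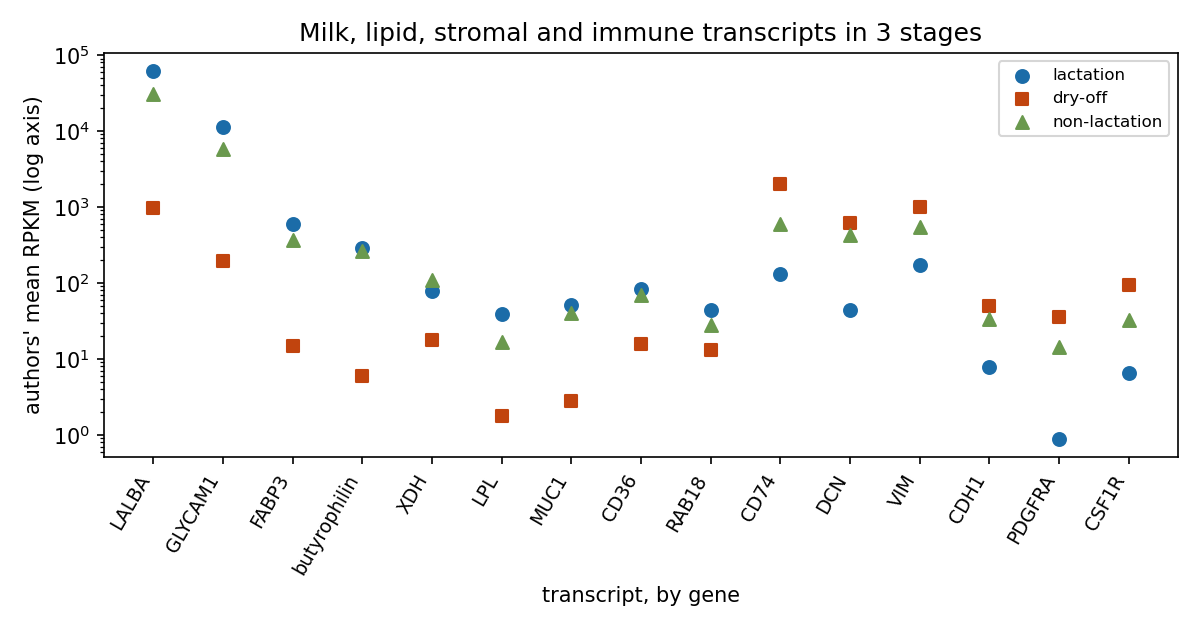
Authors' mean RPKM on a log axis for milk, lipid, stromal and immune transcripts in lactation (circles), dry-off (squares) and non-lactation (triangles), 1 mean per stage with no error. LALBA, GLYCAM1, FABP3, butyrophilin and LPL had their lowest mean in dry-off, and CD74, DCN, VIM, CDH1, PDGFRA and CSF1R their highest.

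**Figure D3:**
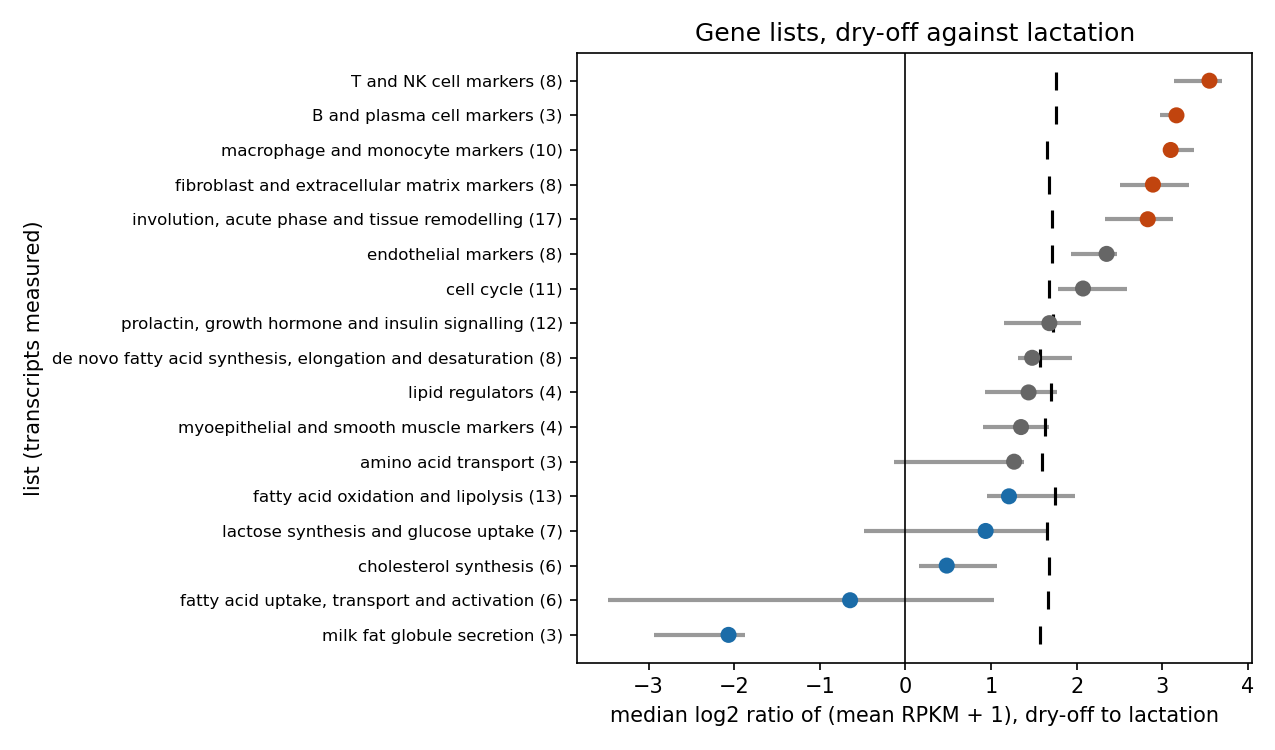
Median log2 ratio of mean RPKM plus 1, dry-off to lactation, for each gene list with at least 3 measured genes (dot), with the interquartile range of its members (grey line) and the median of matched random lists (black tick). Orange dots lie above the upper limit of random lists, blue dots below the lower limit, and grey dots between. Relative to the table median of 1.47 the lists for fatty acid oxidation, cholesterol, lactose and glucose uptake, amino acid transport, myoepithelial markers and lipid regulators turn below 0, and cholesterol and lactose and glucose uptake do so against the ribosomal median too.

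Among 185 KEGG pathways with at least 10 components, proteasome and adherens junction were enriched among transcripts that rose in dry-off. Of 44 proteasome components 42 rose (exact one-sided hypergeometric test, adjusted p = 0.000128), against 63.6% of all components with a pathway, and of 83 adherens junction components 68 rose (adjusted p = 0.0179). The median log2 ratio was 1.84 for proteasome, below the table median of 2.09, and 2.17 for adherens junction, near it. Both enrichments are thus of the number of calls, not of the size of the rise. No pathway passed among the 26 components that fell, by the hypergeometric test, where 7 pathways had an unadjusted p under 0.05. Glycerolipid metabolism came closest, with 3 of 28 components (exact hypergeometric test, adjusted p = 0.167), while 13 of the same 28 components rose.

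Non-lactating glands had means of milk transcripts nearer to lactation than dry-off glands had, and 1 transcript passed the authors' threshold against lactation. A transcript described as ADAM33, a metalloproteinase, rose from 1.33 to 8.01 RPKM in the authors' deposited table (FDR 0.0457), and was named after its values were seen. LALBA had 60951 and 30948 RPKM (FDR 0.203), butyrophilin 288 and 260 RPKM (FDR 0.736) and XDH 77.7 and 110 RPKM (FDR 0.372) in lactation and non-lactation in the authors' deposited table. GHR, the growth hormone receptor, had 1.97 and 8.62 RPKM (FDR 0.112) and CDH1 7.73 and 33.4 RPKM (FDR 0.127) in the authors' deposited table. No list had a member that passed over all transcripts. Adjusted over the list alone, 4 hormone signalling, 4 endothelial, 3 lactose and glucose uptake and 2 amino acid transport genes passed, 1 each of fatty acid synthesis, cholesterol, luminal and neutrophil genes, and 0 of the other lists. The fibroblast and matrix list had its median above all random lists (log2 2.45), and the macrophage, T and NK cell, endothelial and involution lists lay at percentiles 99.98, 99.98, 99.25 and 99.73. Milk fat globule, fatty acid uptake and fatty acid oxidation lay at percentiles 0.245, 0.03 and 2.01. Their log2 medians were −0.33, 0.25 and 0.72, all below the table median of 0.90 on the same scale. With family descriptions uptake and oxidation lay at 15.9 and 62.7, within the limits, as did oxidation with a pseudocount of 0.1 (11.4). The unadjusted p-value was under 0.05 in 3811 transcripts, 3786 of them higher in non-lactation, with a table median log2 ratio of 1.39.

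Against dry-off, non-lactating glands had higher means of milk protein and milk fat globule genes and lower means of all measured T and NK cell, B cell and macrophage genes, and none passed the authors' threshold over all transcripts. Adjusted over the list alone, 3 hormone signalling, 2 B cell and 2 interferon response genes passed, 1 each of fatty acid synthesis, fatty acid uptake, cell cycle and luminal genes, and 0 of the other lists. Butyrophilin had 5.86 RPKM in dry-off and 260 RPKM in non-lactation (FDR 0.206), CD36 15.9 and 68.4 RPKM (FDR 0.154) and the acyltransferase 1/2 transcript 5.01 and 59.2 RPKM in the authors' deposited table. CD74 had 2004 RPKM in dry-off and 588.5 RPKM in non-lactation (FDR 0.184) in the authors' deposited table. A transcript described as collagen of type I, II, III, V or XI had 262 and 637 RPKM (FDR 0.351) in the authors' deposited table, its highest mean being in non-lactation. Milk fat globule, fatty acid uptake, cholesterol and lactose and glucose uptake lists lay at percentiles 99.93, 100, 99.95 and 99.73, with log2 medians of 2.56, 0.93, 0.25 and −0.10. All 3 milk fat globule genes had higher means in non-lactation, against 3 of 6 uptake, 4 of 6 cholesterol and 3 of 7 lactose and glucose uptake genes. T and NK cell, B cell, macrophage and involution lists lay at percentiles 0.01, 0.23, 0.05 and 2.25. With family descriptions the lactose and glucose uptake and involution lists lay within the limits, at 88.0 and 8.08. By the authors' FDR 0 transcripts differed, with a smallest FDR of 0.0534, and 3702 had an unadjusted p-value under 0.05, of which 3516 were lower in non-lactation (table median log2 ratio −0.70).

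Over the 3 stages, 6080 transcripts passed in at least 1 comparison, and 5851 of them were higher in dry-off than in lactation and lower again in non-lactation. A further 166 had a higher mean at each step, 63 had their lowest mean in dry-off (25 of them with the highest in non-lactation), and 0 had a lower mean at each step. Over the whole table the non-lactation mean lay between the other means in 8442 transcripts (92.5%). The authors' own profiles assigned 8396 transcripts, of which 5258 were in profile 14 and 2613 in profile 11. Profile 5 held 84 transcripts, with median RPKM of 16.8 in lactation, 2.55 in dry-off and 12.3 in non-lactation.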

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

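The tests in this part were chosen after the results were seen, except the one on the spread within the non-lactation stage, whose bounds were set before and whose bootstrap was added after.

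The authors' table of correlated transcripts, which no comparison above used, gave a median of 7544 correlated transcripts per transcript, between 93 and 8028 of the 9131; with the criterion not stated, its origin was not tested.

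Most transcripts had higher RPKM in dry-off than in lactation, with a table median log2 ratio of 2.09. Milk transcripts that take reads in lactation would lower all other transcripts by 1 common factor. The table median lay 1.08 log2 above that of ribosomal protein transcripts, whose interquartile range was 0.27. The interquartile range of the table itself was 1.34, larger than this gap. The gap argues against 1 factor as the whole cause only if the choice of transcripts for the table did not raise its median. That was not tested, and 93.8% of its transcripts had p under 0.05 in at least 1 comparison. A lower share of luminal epithelial cells would raise the markers of other cell types alike, but the medians of endothelial, fibroblast, T and NK, B and macrophage lists spanned 2.04 log2, against a median interquartile range of 0.68 within lists, and with 1 added to each mean, as in the list medians above, 1.20 against 0.53. A part of the shift from either source stays open, as does a biological difference between the stages, which was not tested. How transcripts entered the table is not given in the sources used here, and its effect on the split was not tested.

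Non-lactation means lay between those of lactation and dry-off in 92.5% of transcripts, and milk transcripts were among them (LALBA 30948 RPKM against 60951 and 960.4). A fixed mixture of lactation-like and dry-off-like RNA would keep the non-lactation mean within the other means. Of 14 milk and milk fat transcripts, 5 lay above lactation, past the bound of 2 written for this prediction. These were a stearoyl-CoA desaturase, 2 acyltransferase 1/2 transcripts, an acylglycerol phosphate acyltransferase and XDH, but 0 of them had p under 0.05 against lactation. Such a mixture would also place every transcript the same share of the way from dry-off to lactation. That share ran from 0.394 (LPL) to 3.08 (the stearoyl-CoA desaturase). Whether this range exceeds the spread between samples was not tested. Of 623 transcripts highest in non-lactation, 71 (11.4%) had p under 0.05 against both other stages, more than the 5% bound. No transcript had all 3 p-values above 0.141, and how far such a selection raises this share was not tested. A bound that allows for this selection, 2.5% of all described transcripts (319), was not reached. Both written bounds were thus passed. Without an account of spread and selection, the mixture still cannot be told apart from a different state of the gland. Strong differences in milk transcripts between the non-lactation samples would give a coefficient of variation with a median of at least 0.8. If the authors' test was the unequal-variance one, their p-values imply a median of 0.320 over the 14 transcripts, under the 0.4 set beforehand. A bootstrap over transcripts gave a 95% interval of 0.237 to 0.389, and the highest coefficient was 0.626. The transcripts share the same 3 samples, so this interval covers the choice of transcripts and not the spread between samples. The coefficients themselves argue against differences of that size between these samples. The prediction was written for animals, but the labels do not say that the samples came from separate animals. Differences between animals thus cannot be judged from these values. The coefficient was above that of lactation in 11 of 14 transcripts and at least 0.4 in 3. For LALBA it was 0.489 to 0.495, against 0.120 to 0.135 in lactation, so smaller differences between samples stay open. A biological difference between the stages stays open as well and was not tested.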

How the results depend on the processing

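The centred values, the counts by component and by unadjusted p-value, the lists with family descriptions and the pathway test on all transcripts were chosen after seeing the data. The count for dry-off against lactation (6079) was 1505 at an FDR of 0.01 and 2540 with 1 transcript per description, and over all stages (6080) 1505 and 2541, since fewer transcripts are tested or pass. Against lactation, non-lactation had 0 transcripts at an FDR of 0.01 and 3811 at an unadjusted p-value under 0.05, and against dry-off 3702. The share of higher calls was 50.7% against the table median. With all transcripts 8 pathways passed among those that rose and 10 among those that fell; transcripts of 1 component share reads. The 3 counts of lists outside the limits, the stage profiles, the pathway test with another background and the counts at least 2-fold or at a mean of at least 1 RPKM stayed within 1.5 times. List percentiles kept their side of the limits in 40 cases with family descriptions and in 50 with a pseudocount of 0.1. With families 6 came to lie inside: fatty acid oxidation and lactose and glucose uptake (dry-off against lactation), fatty acid uptake and oxidation (non-lactation against lactation), and lactose and glucose uptake and involution (non-lactation against dry-off). Outside came to lie 5: cell cycle in each comparison, myoepithelial (non-lactation against lactation) and fibroblast (non-lactation against dry-off). With families the lists outside the limits numbered 11 (dry-off against lactation), 10 (non-lactation against lactation) and 10 (non-lactation against dry-off). These counts include lists that reach 3 members only with families, which are not named here. With the pseudocount 1 came to lie inside, fatty acid oxidation (non-lactation against lactation).

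Centring on the table median turned the list medians for dry-off against lactation to −0.26 (fatty acid oxidation), −0.98 (cholesterol) and −0.53 (lactose and glucose uptake), for non-lactation against lactation to −0.65 (fatty acid uptake) and −0.18 (fatty acid oxidation), and for non-lactation against dry-off to 0.45 (lactose and glucose uptake). On the ribosomal protein median they were −0.50 (cholesterol), −0.043 (lactose and glucose uptake), −0.15 (fatty acid uptake) and 0.50 (lactose and glucose uptake against dry-off). Lists within the limits changed sign too: on the table median 3 for dry-off against lactation, 2 for non-lactation against lactation and 5 for non-lactation against dry-off, where the ribosomal protein median turned 6. Log2 ratios for dry-off against lactation became −0.37 (CD14), −0.43 (an E74-like factor 3/5), −0.33 (IGF1R), −0.76 (LIPE), −0.61 (MCAT), −0.74 (NSDHL), −0.16 (OXSM), −0.015 (PCNA), −0.96 (SLC27A1), −0.25 (SLC27A3), −0.56 (SLC3A2), −1.004 (SOCS2), −0.85 (SREBF2) and −1.31 (a long-chain acyl-CoA synthetase, −0.23 on the ribosomal protein median) on the table median. These changes of sign come from subtracting the shift itself.

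No paired analysis was possible because the deposited columns hold stage means with no replicate number. Not run for the same reason were leaving out a sample, other filters before testing, quantile normalization, fits on other sample sets and an estimated correlation. Depth per sample was not analysed here, so what depth limits is unknown.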

Other observations

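The tests on the pathway column in this part were chosen after the result was seen; those on the authors' p-values were written before.

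Ribosomal protein transcripts had a smaller shift than the table. Of 43 such transcripts 17 rose in dry-off and 1 fell by the authors' FDR, with a median log2 ratio of 1.00, an interquartile range from 0.89 to 1.16, and medians of 0.40 in non-lactation against lactation and −0.61 in non-lactation against dry-off. Their median lay below that of the table.

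Descriptions of E74-like factors 3/5, epithelial transcription factors that share a family description, went opposite ways between components in the authors' deposited table. One fell from 81.9 to 24.8 RPKM in dry-off (FDR 0.0314) and had 70.4 RPKM in non-lactation, and another rose from 5.48 to 17.2 RPKM (FDR 0.0385) and had 8.39 RPKM in non-lactation, a rise that lay 0.43 log2 below the table median. Long-chain acyl-CoA synthetase descriptions also differed by component in the authors' deposited table. One rose from 1.61 to 29.4 RPKM (FDR 0.00944), and another from 10.03 to 17.2 RPKM (FDR 0.0474) with 25.6 RPKM in non-lactation, the latter below both the table and the ribosomal protein median.

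The authors' p-values may come from a two-sided test with unequal variances on 3 against 3 untransformed RPKM values. For 185 transcripts at 0 in lactation, the p-value of dry-off against non-lactation was computed from the other p-values, and it lay within 1% of the deposited value in 100% of them; with equal variances it did so in 0.541%. The pathway column beside the descriptions shared 1.07% of its memberships with the separate pathway table, against 1.45% on average after shuffling, while 238 of 250 pathways had equal sizes, a result consistent with a column attached to other transcripts.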
